A study of Rattus norvegicus with 8 samples.

How the data were processed

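Peripheral whole blood of male Wistar rats was profiled on an Affymetrix rat expression array, with 4 arrays for a high-fat diet and 4 for the same diet with 1% mulberry leaf powder. Per the labels, the diets were given for 8 weeks and blood was taken on day 56 after a night of fasting. Each diet group held 10 rats, total RNA was isolated with TRIzol LS and purified on an RNeasy column, and 200 ng of it was turned into biotinylated aRNA with the GeneChip IVT Express kit. The labels call the arrays of a diet biological replicates and do not say whether each array holds the RNA of 1 rat or of a pool, so p-values measure the spread between these samples. Which rats of a group were used is also not stated. A normal-diet group named in the design was not analysed here.

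The values deposited by the authors are read as log2 probe set summaries, because each array spans about the same range, from 5.17 to 15.26, with no zeros. The summary and normalization methods are not given in the sources used here. The spread of a probe set between arrays was far smaller than log2 intensities usually show: the median SD over the 8 arrays was 5.31e-06, 99.4% of the probe sets had an SD under 0.001, and 18 had one above 0.01. The scale between arrays was therefore compressed by an unknown amount that may differ between probe sets, and a difference was not read as an ordinary fold change. Differences are given in SD units, the difference between the diet means divided by that probe set's SD over the 8 arrays, which does not change when a probe set is rescaled. Signal over background and detection calls were not used here, so the precision is limited by the number of arrays.

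The table held 31099 probe sets, of which 57 manufacturer controls were left out of the tests and 31042 were tested. Gene names came from the annotation of the platform, with the gene numbers checked against RefSeq (assembly GRCr8). In all, 20826 tested probe sets named 1 gene, 436 named several and 9780 were unnamed here. Of the first kind, 20758 matched RefSeq by gene number. Probe sets naming several genes were not used for naming. For gene lists, 1 probe set per gene was kept, the one with the highest mean over the arrays, giving 14217 genes.

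Each probe set was tested between the diets with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. No further normalization was applied. The 27 gene lists, 9 of cell type markers and 18 of pathways, were tested with camera at its preset correlation of 0.01, adjusted over the lists. They held 1013 symbols, of which 834 were matched. Camera with a correlation estimated per list and fry were alternatives. As a test over arrays, the mean of a list's genes, each centred on its mean, was compared between diets with a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286. List scores printed in the text are means of genes scaled to unit SD. Exact permutation p-values printed with those scores are for the scaled genes. Those for centred genes without scaling are named as on the deposited scale.

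The genes named in the text were chosen by a rule. Because no probe set passed the threshold, the rule named the 24 genes of smallest unadjusted p, none of which passed, and then the 4 members of smallest unadjusted p in each list past its threshold, with fewer or none for other lists. Any other gene is said to have been chosen after its values were seen. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. Those alternatives were quantile normalization, median centring, a filter on dim probe sets, a replicate block, leaving out each array, blood cell scores as covariates, other variance models, array weights, a rank product over all 16 between-diet differences with 100 permutations (Python 3.11.15, numpy 2.4.6), other thresholds, other rules for genes with several probe sets, and other scores. Added after the data were seen were the 18 hybridization control probe sets and the 24 polyA control probe sets as covariates, centring on the median deviation in SD units, and lists without probe sets that can match several transcripts.

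The steps were tested on simulated data with the real means and within-group SDs. Among 31042 simulated probe sets, the limma fit called 22% of those moved by 4 within-group SDs, 94% at 8, 98% at 16 and 100% at 32, with 14 unmoved probe sets called. Camera on 14217 simulated, independent genes called a list lowered by 1 SD in 20 of 20 runs and no unmoved list. Genes of real lists were correlated, with an estimate of 0.423 for the monocyte list, so this says little of false calls on real lists. In 5000 simulated probe sets without any difference between diets but with unequal spread, the rank product called 98.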

Results

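Transcript levels in whole blood were compared between male Wistar rats fed a high-fat diet and rats fed that diet with 1% mulberry leaf powder for 8 weeks, with 4 arrays per diet. The comparison asks how eating mulberry leaf alters gene expression in blood cells. Each array gave 31042 tested probe sets. Differences are given as mulberry minus high-fat in SD units, where 1 unit is the SD of that probe set, or of each list member, over the 8 arrays, because the deposited values were compressed between arrays.

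Ribosomal protein transcripts stood lower in the mulberry group, 41 of the 42 measured genes of the cytosolic ribosome having lower means, although the place among other genes turned under quantile normalization, and median centring, which shifts all genes of an array alike, turned the score higher. Markers of antigen presentation, interferon response, natural killer cells and B cells also stood lower than other genes. So did genes of the proteasome and of the heat shock response, while platelet markers stood higher. Quantile normalization or median centring turned the interferon, proteasome, heat shock and platelet lists in score or in place among other genes. After median centring camera still called the interferon, proteasome and heat shock lists lower (adjusted p = 4.77e-35, 0.0327 and 0.000443), and did not call the platelet list (0.841). Median centring also reduced the MHC class II, natural killer and B cell score differences to -0.16, -0.00453 and -0.0373. Camera still called these lists lower there (adjusted p = 1.6e-24, 3.71e-34 and 1.6e-24). Median centring shifts probe sets upward with mulberry, by several times a typical SD, so lower scores were turned or reduced by construction. The shift is smaller in SD units for probe sets of wide spread, so camera's placements there cannot separate spread from diet. Quantile normalization ended the call of all 8 lists, leaving score differences from -0.398 (natural killer) to 0.287 (platelet). It allows only values of a common sorted array, with neighbours 6.17e-05 apart in the median, against a median probe set SD of 5.31e-06. Smaller differences can be lost there by construction, so the ended calls do not decide whether these lists differed. The ribosomal list alone kept its call when the correlation between its genes was estimated. For the interferon and called cell type lists the estimates ran from 0.234 (MHC class II) to 0.396 (B cell). They were -0.00429 for heat shock and -0.0106 for proteasome, below the preset 0.01. The loss of these last calls is therefore no sign of correlated genes. No single probe set passed the threshold.

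The ribosomal list scored 0.612 ± 0.63 (SD, n = 4) in the high-fat arrays and -0.612 ± 0.373 (SD, n = 4) in the mulberry arrays. On the deposited scale its difference was only -1.61e-05, against -0.00126 for the MHC class II list. The compression may differ between probe sets, so the sizes on that scale cannot be compared as fold changes. All 4 mulberry arrays lay below all 4 high-fat arrays (difference -1.22 SD units, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow). After adjustment over the 27 lists the exact permutation p was 0.771 for the scaled genes and 0.386 on the deposited scale. By camera in limma the adjusted p was 9.85e-25 at the preset correlation, and adjusted p = 0.000416 with an estimated correlation. Individually, 23 of the 42 genes had an unadjusted p under 0.05, none passed over all probe sets, and 3 passed when adjusted over the list alone. These 3 were Rps6, a small-subunit protein phosphorylated downstream of mTOR signalling (-1.66 ± 0.336, SE), Rpl23a of the large subunit (-1.67 ± 0.347) and Rps16 of the small subunit (-1.65 ± 0.347). Rpl7a differed by -1.53 ± 0.415, and Rpl21 was the 1 member with a higher mean (0.387 ± 0.703, 0 after quantile normalization, chosen after its values were seen). With the deposited values quantile normalized the list was no longer called (limma camera adjusted p = 0.939, difference -0.0457), and median centring turned the score difference to 0.76 while camera still placed the list below other genes. Rps6, Rpl23a, Rps16 and Rpl7a had a difference of 0 after quantile normalization and turned to 0.735, 0.982, 0.877 and 0.703 after median centring. The hybridization controls, bacterial transcripts meant to be added in fixed amounts, averaged -0.558 ± 0.856 in the high-fat arrays and 0.558 ± 0.635 in the mulberry arrays (SD units, n = 4 each, exact permutation p = 0.114). The polyA controls, bacterial transcripts meant to be added before labelling, averaged -0.49 ± 0.899 and 0.49 ± 0.699 (n = 4 each, exact permutation p = 0.171). The ribosomal difference was -0.733 ± 0.406 (SE) with the hybridization controls in the model and -0.952 with the polyA controls.

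Of the 13 measured genes for MHC class II antigen presentation, all 13 had lower means in the mulberry group. The list score was 0.435 ± 0.724 (SD, n = 4) in the high-fat and -0.435 ± 0.487 (SD, n = 4) in the mulberry arrays. The exact permutation p was 0.0857 for the scaled genes and 0.171 on the deposited scale. Mulberry replicates 1 and 3 scored -0.657 and -1.01, against 0.00841 and -0.0762 for replicates 2 and 4. High-fat replicate 3 scored -0.642. The limma camera adjusted p was 0.000102, and adjusted p = 0.23 with an estimated correlation. Cd80, a costimulatory ligand for T cells, differed by -1.16 ± 0.578 (1.03 after median centring), and RT1-Ba, a class II alpha chain, by -1.08 ± 0.587. Rfxap, a subunit of the class II promoter regulator, differed by -1.1 ± 0.605 (1.11 after median centring), and a probe set of the beta chain gene RT1-Bb by -1.07 ± 0.589. No member passed when adjusted over the list alone. A different RT1-Bb probe set, chosen after its values were seen, differed the opposite way, by 1.06 ± 0.591. After quantile normalization Cd80 and Rfxap had a difference of 0, and with the hybridization controls in the model the list was not called (camera adjusted p = 0.0783, difference -0.598).

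Among 41 type I interferon response genes, 34 had lower means with mulberry (score difference -0.471, 0.0966 after median centring, limma camera adjusted p = 0.000959, and adjusted p = 0.503 with an estimated correlation). Irf7, a transcription factor of interferon induction, differed by -1.24 ± 0.538, Mx2, an antiviral GTPase, by -1.12 ± 0.576, and Ifi44 by -1.16 ± 0.568 (0 after quantile normalization and 0.905 after median centring). Tap2, a peptide transporter of class I antigen presentation, had a higher mean (1.21 ± 0.548). The mulberry arrays themselves ranged from -0.994 to 1.34 on this score, and the call ended without mulberry replicate 2 or 3 (camera adjusted p = 0.173 and 0.133), while without mulberry replicate 4 the difference was -1.17 (camera adjusted p = 3.25e-21). With the hybridization controls in the model the interferon difference turned to 0.0781.

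Natural killer and cytotoxic lymphocyte markers had lower means in 24 of 29 genes (score difference -0.521, limma camera adjusted p = 0.001, and adjusted p = 0.503 with an estimated correlation). The killer lectin-like receptor Klrc1 differed by -1.21 ± 0.551 (0.749 after median centring), Klrk1 by -0.987 ± 0.61, Klrb1c by -0.966 ± 0.616 (0.707 after quantile normalization and 1.04 after median centring) and the chemokine gene Xcl1 by -0.944 ± 0.62. High-fat replicate 4 alone scored 1.55 on this list, and without it the call ended (adjusted p = 0.366). With the hybridization controls in the model the difference was -0.00184. B cell markers were lower in 16 of 18 genes (score difference -0.463, adjusted p = 0.0242, and adjusted p = 0.604 with an estimated correlation), among them the IgE receptor gene Fcer2 (-1.03 ± 0.599), the IgM receptor gene Fcmr (-0.981 ± 0.611), Ms4a1, which encodes CD20 (-0.955 ± 0.617, 0 after quantile normalization), and Fcrla (-0.886 ± 0.632). The B cell call ended without high-fat replicate 1 or 2 or mulberry replicate 1 or 3 (camera adjusted p = 0.2, 0.327, 0.289 and 0.279), and without high-fat replicate 3 the difference was -0.813 (adjusted p = 0.000533).

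Platelet markers were the list that stood higher, with higher means in 23 of 26 genes (score difference 0.552, limma camera adjusted p = 0.000992, and adjusted p = 0.503 with an estimated correlation). After median centring the score difference was 0.899, but the camera direction was below other genes and the list was not called (adjusted p = 0.841). Alox12, the platelet 12-lipoxygenase, differed by 1.27 ± 0.528, the integrin gene Itga2b by 1.24 ± 0.538, the ADP receptor gene P2ry12 by 1.18 ± 0.557 and Tubb1, the tubulin of the platelet marginal band, by 1.15 ± 0.566. After quantile normalization Itga2b and Tubb1 had a difference of 0, and P2ry12 turned to -0.0477. The score rested on mulberry replicate 4 at 1.61 and high-fat replicate 4 at -1.03, and the call ended without the first (adjusted p = 0.401) or the second (adjusted p = 0.124).

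**Figure D1:**
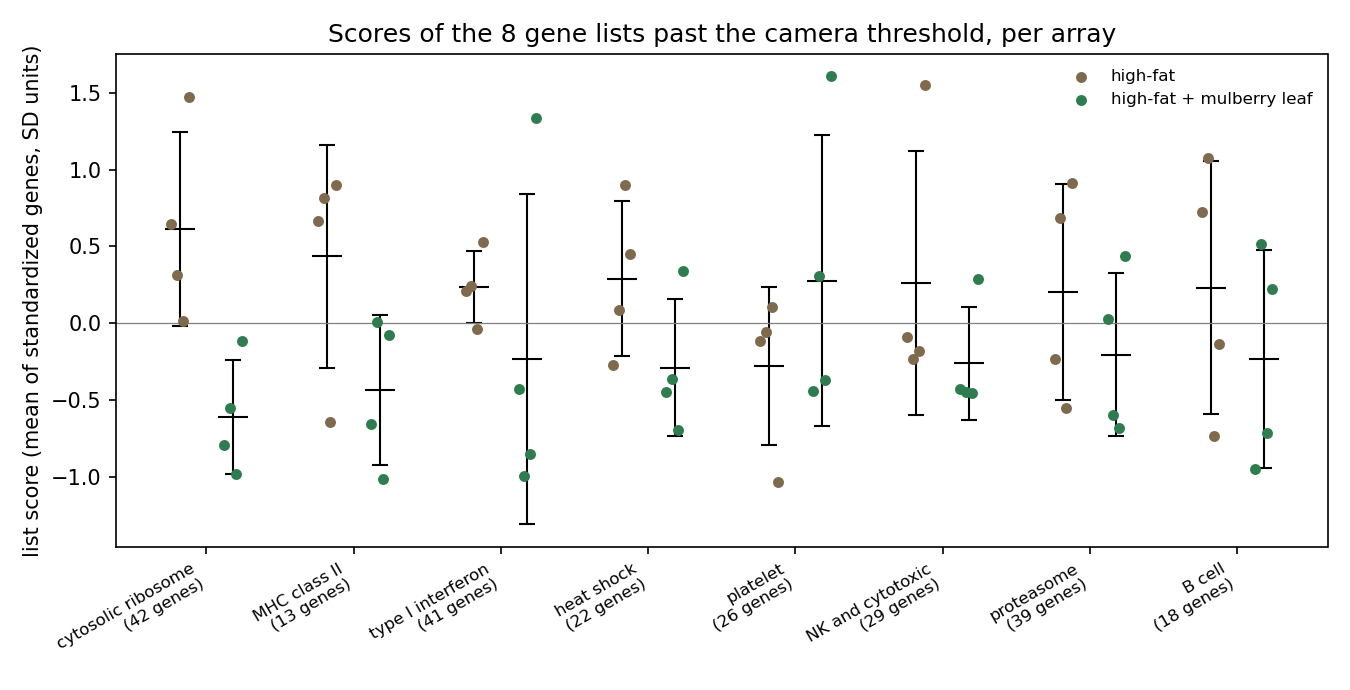
List score per array in SD units (vertical axis) for the 8 lists past the camera threshold, with 4 high-fat and 4 mulberry arrays per list as points and mean ± SD as bars. The ribosomal scores of the diets did not overlap, while in the interferon and platelet lists mulberry replicate 4 sat apart at 1.34 and 1.61; the ribosomal, interferon, heat shock and proteasome score differences turned positive after median centring, and the proteasome one also after quantile normalization.

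Proteasome subunit genes had lower means in 29 of 39 cases (score difference -0.408, 0.257 after quantile normalization and 0.881 after median centring, limma camera adjusted p = 0.00458, and adjusted p = 0.08 with an estimated correlation). The immunoproteasome activator gene Psme1 differed by -1.26 ± 0.531, Psmb7 by -1.24 ± 0.54 and Psma7 by -1.09 ± 0.591, whereas Psmd4, the ubiquitin receptor, had a higher mean (1.34 ± 0.501). After quantile normalization Psme1, Psma7 and Psmd4 had a difference of 0 and Psmb7 turned to 0.749, and median centring turned Psmb7 to 0.687 and Psma7 to 1.1. This call ended without high-fat replicate 2 or 4 or mulberry replicate 2 or 3 (camera adjusted p = 0.0954, 0.366, 0.125 and 0.19), and without high-fat replicate 3 the difference was -0.679 (adjusted p = 0.000158). Heat shock genes were lower in 18 of 22 cases (score difference -0.58, 0.698 after median centring, adjusted p = 0.000959, and adjusted p = 0.078 with an estimated correlation), led by the HSP40 cochaperone genes Dnajb4 (-1.45 ± 0.454) and Dnajb1 (-1.42 ± 0.467), Cryab (-1.21 ± 0.553, 0.751 after median centring) and Hspa4 (-1.19 ± 0.564, 0.716 after quantile normalization and 1.08 after median centring). The heat shock call ended without high-fat replicate 3 (camera adjusted p = 0.102).

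In all, camera called 8 of the 27 lists, 7 lower and 1 higher, and 1 of them with an estimated correlation. Camera gave at least 8 calls in 21 of the 35 splits of the arrays into 4 and 4, the real one among them. After quantile normalization it called 0, after median centring 13, and with the hybridization controls in the model 4 (platelet and neutrophil markers higher, ribosomal and heat shock genes lower). With the polyA controls in the model it called 6, all lower, losing the natural killer, B cell and platelet lists (adjusted p = 0.337, 0.406 and 0.347) and gaining oxidative phosphorylation. Fry called 0 (lowest adjusted p = 0.429). The exact permutation test over arrays, on the deposited scale, called 0 after adjustment (lowest adjusted p = 0.386). In that test 16 lists would have had to reach the smallest p.

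**Figure D2:**
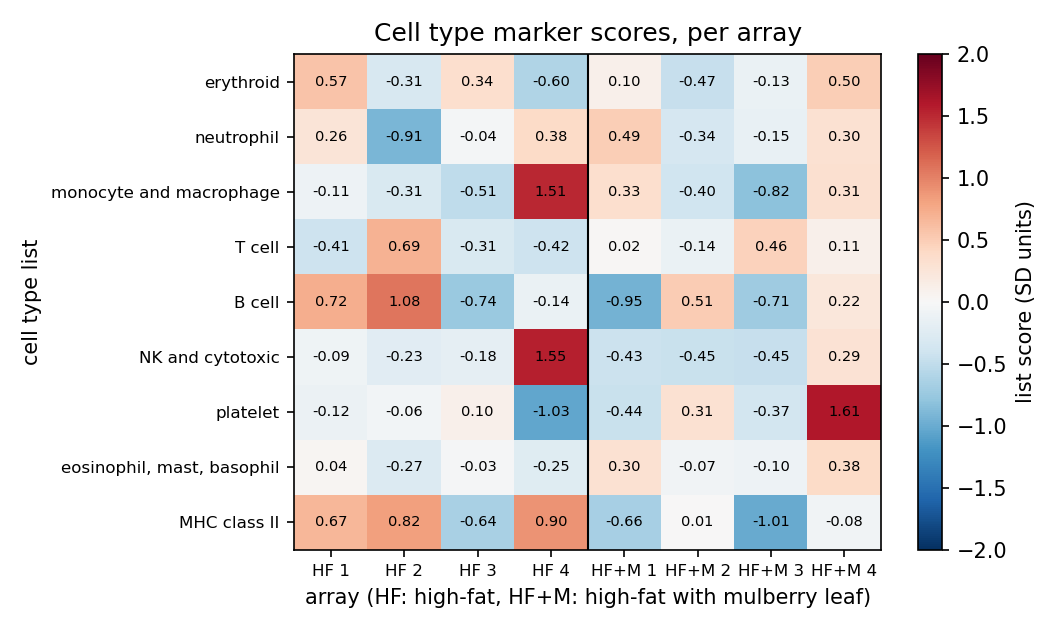
Scores of the 9 cell type marker lists (rows) on the 8 arrays (columns) in SD units, as colours and printed values. High-fat replicate 4 had the highest monocyte (1.51) and natural killer (1.55) scores and the lowest platelet score (-1.03).

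The other cell type lists were not called by camera on the deposited values, while after median centring it placed the erythroid and monocyte lists below other genes (adjusted p = 1.9e-14 and 8.3e-27). Those placements cannot separate spread from diet, because the common shift is smaller in SD units for probe sets of wide spread. Score differences in SD units were 0.000446 for erythroid markers (adjusted p = 0.951), 0.155 for neutrophil (0.416), 0.223 for T cell (0.352) and 0.258 for eosinophil, mast cell and basophil markers (0.27). Monocyte and macrophage markers had a difference of -0.289 (adjusted p = 0.134; 0.084 after median centring), which turned to 0.189 without high-fat replicate 4. It was called without high-fat replicate 2 or 3 or mulberry replicate 1 (adjusted p = 0.0168, 0.0201 and 0.0161), and the T cell list was called higher without high-fat replicate 2 (adjusted p = 0.016).

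The lists for fat and sugar metabolism were not called on the deposited values either. Fatty acid oxidation and PPAR target genes differed by -0.292 in score (0.96 after median centring, limma camera adjusted p = 0.0723), with the mitochondrial beta-oxidation gene Echs1 at -1.36 ± 0.507 (0.995 after median centring) and the carnitine carrier gene Slc25a20 at 1.34 ± 0.501. On the deposited scale this list and the ribosomal list were the 2 that reached the smallest exact permutation p (0.0286, and 0.386 after adjustment). That scale gives genes of wide spread the most weight. With genes scaled to unit SD, the exact permutation p of the fatty acid oxidation list was 0.257. Camera called it without high-fat replicate 1 or 3 or mulberry replicate 2 (adjusted p = 0.0211, 0.048 and 0.0442), and in the brighter probe sets (0.0487). Cholesterol synthesis differed by -0.314 (0.0398 after quantile normalization and 1.08 after median centring, camera adjusted p = 0.195), and was called lower with the mean of a gene's probe sets (-0.418, adjusted p = 0.0222). Fatty acid synthesis differed by 0.135 (0.594). Glycolysis differed by -0.0794 (0.594), and after median centring by 0.732, when camera placed it below other genes (adjusted p = 0.00156). Insulin and glucose signalling differed by 0.00525 (0.951). Oxidative phosphorylation genes had lower means in 52 of 69 cases (difference -0.246, 0.21 after quantile normalization and 1.07 after median centring, adjusted p = 0.0573), and were called lower without high-fat replicate 1 or 3 or mulberry replicate 1 or 4 (adjusted p = 0.0339, 0.00075, 0.00126 and 0.000328). Without high-fat replicate 4 the difference was only -0.00109 (adjusted p = 0.987), and it also shrank without mulberry replicate 2 or 3 and with the hybridization controls in the model. They were also called lower with the erythroid score (0.0465) or the polyA controls (0.0181) in the model, with the mean of a gene's probe sets (0.0218), and without probe sets that can match several transcripts (0.0432).

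The remaining stress and regulatory lists were not called by limma camera on the deposited values, while after median centring it placed the inflammation, NRF2 and unfolded protein response lists below other genes (adjusted p = 3.85e-07, 0.0163 and 0.0006), although their scores turned positive. These placements too cannot separate spread from diet. Score differences were -0.142 for NF-kB inflammation (adjusted p = 0.352), -0.0163 for NRF2 antioxidant genes (0.951), -0.108 for the unfolded protein response (0.594), and 0.0285 for the glucocorticoid response (0.951). They were 0.209 for the circadian clock (0.374), -0.0263 for the cell cycle (0.845), 0.211 for autophagy and mitophagy (0.243, and 0.0442 without mulberry replicate 2) and -0.0955 for reticulocyte ubiquitin genes (0.764).

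At the level of single probe sets, limma called 0 of 31042 (lowest adjusted p = 0.569), and 1352 (4.36%) had an unadjusted p under 0.05, against 1552 expected by chance, 852 of them higher and 500 lower with mulberry. After median centring the 2492 such probe sets were 2465 higher and 27 lower, and after quantile normalization the 534 were 275 higher and 259 lower. The diets did not overlap in 781 probe sets (2.52%), against 2.86% by chance. A rank product over the deposited values, which weights probe sets by their spread, called 345 at a false discovery rate under 0.05. Of these, 175 were called higher and 175 lower, 5 of them both ways. In 16 of the 35 splits of the arrays into 4 and 4, the real one among them, at least as many were called as in the real one.

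The 24 named genes of smallest unadjusted p, none of which passed, are given as single values, and no shared function was tested among them. Sin3b, a scaffold of histone deacetylase complexes, differed by 1.8 ± 0.205, the histone variant gene Macroh2a2 by 1.73 ± 0.313, Rbbp6 by 1.68 ± 0.325, the zinc finger gene Zfp68 by -1.81 ± 0.218, and Pygo2, a coactivator in Wnt signalling, by -1.68 ± 0.326. The m6A reader gene Ythdf3 differed by -1.68 ± 0.318, and Mdm2, which encodes the ubiquitin ligase of p53, by -1.68 ± 0.345. Mad2l1 of the spindle checkpoint differed by -1.68 ± 0.344 and the death effector gene Dedd by 1.68 ± 0.322.

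Further genes of the 24 were Sh3gl2, an endophilin of vesicle endocytosis (1.8 ± 0.201), Galnt16, an O-glycosylation enzyme (1.81 ± 0.249), and the oxysterol-binding protein gene Osbpl1a (1.67 ± 0.32). Next to them stood Vat1 (1.77 ± 0.317), the zinc transporter gene Slc30a4 (-1.75 ± 0.271) and Pet100, an assembly factor of cytochrome c oxidase (-1.79 ± 0.217). The others were Plaur, the urokinase receptor gene (1.72 ± 0.329), the G protein gene Gnal (1.65 ± 0.339), Rem1 (1.7 ± 0.334), Calml4 (1.68 ± 0.317), Sash3, a lymphocyte adaptor gene (-1.68 ± 0.314), and the ubiquitin protease gene Usp34 (-1.7 ± 0.302). Ccdc149 (1.73 ± 0.319), Bglap (1.65 ± 0.34) and Rps6 completed the set. Of these, Slc30a4, Vat1, Ccdc149, Sash3, Calml4, Rem1 and Gnal turned direction after quantile normalization, Sh3gl2, Galnt16, Macroh2a2, Pygo2 and Rps6 had a difference of 0 there, and Zfp68, Pet100, Slc30a4, Sash3, Ythdf3, Pygo2, Rps6, Mad2l1 and Mdm2 after median centring.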

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

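The tests of the ribosomal list, the RT1-Bb probe sets and high-fat replicate 4 below, and the split count of the rank product, were chosen only after the result was seen. The other split counts were planned before they were run, but the ribosomal list was singled out after its camera p was known, and the count for the strongest list was added after the first counts. An array was singled out where its gap to the nearest of its diet took up nearly the whole range of the 4 arrays, which chance gives in about 1 in 20 groups. Of 200 groups of 4 arrays looked at, 15 showed this, against 10 by chance, and 6 of the 15 were in genes chosen because their values looked unusual.

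Chance is argued against for the lower ribosomal list only at the smallest share that 35 splits can give, and is not excluded. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave so small a camera p for the list (25.4 as minus log10, highest other 16.6). For the smallest p of any of the 27 lists, 1 of 35 did so (highest other 20.2). Over the 27 lists the adjusted p for the ribosomal list was 0.771 by the exact permutation test (0.386 on the deposited scale) and 0.429 by fry. An effect of the diet stays open. A shift of bright probe sets is argued against, since 10000 random lists matched on level ranged from -0.294 to 0.526, with a median of 0.132. The list's difference of -1.22 lay at percentile 0 of them, but the list was singled out for that difference. A difference in hybridization stays open: with the hybridization controls in the model the difference was -0.733 ± 0.406 (SE), under 2 SE from 0, although camera still called the list (limma camera adjusted p = 3.97e-09); sample preparation stays open too, since the polyA controls differed the same way, with a ribosomal difference of -0.952 with them in the model. A lower share of lymphocytes, whose ribosomal transcripts are abundant, also cannot be told apart, because the T cell score difference of 0.223 ± 0.296 (SE) leaves both signs possible and the B cell and natural killer lists, which camera called lower, differed by -0.463 ± 0.543 and -0.521 ± 0.467 (SE).

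The RT1-Bb probe sets lay apart in opposite directions: one read 6.06 in mulberry replicates 1 and 3 and less on the other 6 arrays, and the other was lowest in the same arrays, at 7.97. The probe sets lay on the same side of their medians on 2 of 8 arrays, which restates why they were singled out, so a change in the amount of RT1-Bb transcript stays open. Rats carrying different RT1 haplotypes stay open too. With RT1-Bb itself left out, 4 of the 115 named probe sets among the 150 of largest spread were RT1 genes, against 29 of 20824 overall (two-sided Fisher's exact p = 1.88e-05). Other immune genes, such as Gzmb, Isg15 and Csf1r (picked after their values were seen), were also among the 150. The count is therefore not particular to haplotypes and does not decide. A true difference in antigen presentation with the diet stays open and was not tested.

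High-fat replicate 4 scored 1.55 on the natural killer list, where the other high-fat arrays lay between -0.232 and -0.091, and 1.51 on the monocyte list. It was also the highest array on the ribosomal (1.47), unfolded protein response (0.936), oxidative phosphorylation (0.91), proteasome (0.91) and MHC class II (0.898) lists. The same held for the inflammation (0.778), cholesterol synthesis (0.653) and fatty acid oxidation (0.447) lists. A lower share of the main blood cell types, which would raise all other types alike, stays open. The monocyte score exceeded the platelet score on that array by 2.54 SD units, but the array was singled out for these scores. Its erythroid score was also the lowest of any array (-0.596), while its T cell score was the lowest too (-0.42). A shift of bright probe sets is argued against. Random lists matched on level had a median score of only 0.14 on that array, so bright probe sets were not raised there in general. The monocyte score lay at percentile 100 of the 10000, which decides nothing by itself. The array was singled out for this score, and genes of the monocyte list were correlated (estimate 0.423), unlike randomly drawn ones. Its hybridization and polyA controls were low (-1.07 and -1.23), though lower still on high-fat replicate 1 (-1.44 and -1.31), so another technical property of the array, its mix of cells and their state all stay open and were not tested.

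The same array stood apart in Xcl1 (2.13), Itga2b (-1.66) and Ldhb (1.17), and mulberry replicate 4 in the natural killer list (0.289) and Itga2b (1.97), all in SD units. High-fat replicate 2 stood apart in the T cell list (0.689) and Rbbp6 (-0.303), and high-fat replicate 3 in the MHC class II list (-0.642) and Psma7 (-0.674). High-fat replicate 1 stood apart in 3 genes chosen for it after the values were seen, Xpo7 (2.46, deposited value 8.73 against 8.31 on the other high-fat arrays), Tmcc2 (2.45) and Gypc (2.35). Mulberry replicate 1 stood apart in Ctrb1, which encodes the pancreatic enzyme chymotrypsinogen (2.47, deposited value 6.95), and in Ldhb (0.663), both also chosen after their values were seen.

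Counts over many genes or lists did not exceed those of other splits. With a real count of 0 probe sets past the adjusted threshold, all 35 of 35 splits had to give as many (highest other 1), which decides nothing. At an unadjusted p under 0.05, 18 of 35 gave at least 1352 (highest other 5204). For lists, 21 of 35 gave at least 8 (highest other 15). Chance cannot be excluded for these last 2 counts. The split with 5204, picked as the highest, set high-fat replicates 1 and 3 and mulberry replicates 2 and 3 against the rest. Whether it reflects a structure of the samples apart from diet was not tested. For the rank product, 16 of 35 splits called at least the 342 probe sets that the real one gave with 10 permutations (highest other 816), and 254 of its 345 calls were among the 600 probe sets of largest spread.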

How the results depend on the processing

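Chosen after the data were seen were the hybridization controls and the polyA controls as covariates, centring on the median deviation in SD units, and the lists without probe sets ending in _s_at, _x_at or _a_at. The limma count of 0 probe sets stayed 0 without any 1 array and in all other settings except quantile normalization (12), an unadjusted p under 0.01 (247) and the rank product (345). The count of 8 lists became 0 with quantile normalization, 13 with median centring, 1 with an estimated correlation, 0 with fry and 4 with the hybridization controls; it was 6 with the polyA controls. Without 1 array it was 5 to 10; it was 5 without high-fat replicate 4 or mulberry replicate 3. The exact permutation count of list scores was 0 in every setting run, which shows little stability, because 16 lists would have to reach the smallest p; within replicate numbers the smallest p is 0.125, so none can pass. Whether replicate numbers pair the arrays cannot be told: deviations of same-numbered arrays correlated at -0.0454, -0.0491, 0.239 and 0.155. Arrays 1 and 2 correlated better with another number (up to 0.116 and 0.114). Arrays 3 and 4 correlated best with their own (other numbers up to 0.0645 and 0.139). With a replicate block 0 probe sets, 10 lists and 0 list scores passed. The monocyte and oxidative phosphorylation lists were gained there (limma camera adjusted p = 0.0072 for both). A pseudocount was not run, because the values are already log2. Of 1195 other values of genes and lists, 1047 kept direction and side of the threshold, 27 lost it, 9 gained it, 92 turned, in score or in camera direction, and 20 became 0. Other variance models, the replicate block, fry and an estimated correlation leave the differences unchanged by construction. No named gene passed in the main fit either, so the number kept shows little stability.

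Quantile normalization and median centring turned 64 of these 92. Median centring adds 1 shift to all probe sets of an array, on average upward with mulberry and several times the median SD, so lower genes and scores that it turned higher were turned by construction and tell nothing of those genes or lists. The shift is smaller in SD units for probe sets of wide spread, so camera's placements after it cannot separate spread from diet. Array medians over the 31042 tested probe sets ranged over 9.36e-05 (0.000145 over all 31099) and their mean was lower by 3.45e-05 with mulberry, against a median SD per probe set of 5.31e-06, whereas the arrays' median deviations ranged over only 7.9e-07. After quantile normalization 17.3% of the probe sets held 1 value on all arrays, and by construction the others can take only values of the common sorted array, whose neighbours lie 6.17e-05 apart in the median. Sash3, Calml4, Rem1 and Klrb1c share a size of 0.707 after it. That size results when a single array differs and all others hold the same value, so these turns rest on a step in a single array. Whether this construction turned each of the other values below was not tested. Values are in SD units, mulberry minus high-fat. Quantile normalization gave list scores of -0.0538 (erythroid), -0.0379 (inflammation), 0.21 (oxidative phosphorylation), -0.0457 (ribosome), 0.257 (proteasome), 0.0398 (cholesterol synthesis), 0.0937 (glycolysis), -0.0203 (NRF2), -0.12 (glucocorticoid) and 0.00047 (ubiquitin). The genes it turned were Slc30a4 (1.17), Vat1 (-0.506), Ccdc149 (-0.898), Sash3 (0.707), Calml4 (-0.707), Rem1 (-0.707), Gnal (-0.423), Klrb1c (0.707), P2ry12 (-0.0477), Psmb7 (0.749), Hspa4 (0.716) and Acot2 (0.303). It left 20 genes with a difference of 0: Sh3gl2, Galnt16, Macroh2a2, Pygo2, Rps6, Ms4a1, Itga2b, Tubb1, Cd80, Rfxap, Ifi44, Rpl23a, Rps16, Rpl7a, Psmd4, Psme1, Psma7, Cxcr4, Map1lc3a and Rpl21. Median centring turned the lists erythroid (0.421), neutrophil (0.976), monocyte (0.084), platelet (0.899), interferon (0.0966), inflammation (0.625), oxidative phosphorylation (1.07), ribosome (0.76), proteasome (0.881), fatty acid oxidation (0.96), cholesterol synthesis (1.08), glycolysis (0.732), NRF2 (0.81), unfolded protein response (0.699), heat shock (0.698), glucocorticoid (0.812), cell cycle (1.06) and ubiquitin (0.857). It turned Zfp68 (0.929), Pet100 (0.644), Slc30a4 (0.85), Sash3 (0.101), Ythdf3 (0.504), Pygo2 (0.817), Rps6 (0.735), Mad2l1 (0.988), Mdm2 (1.00), Klrc1 (0.749), Klrb1c (1.04), Cd80 (1.03), Rfxap (1.11), Ifi44 (0.905), Rpl23a (0.982), Rps16 (0.877), Rpl7a (0.703), Psmb7 (0.687), Psma7 (1.1), Cryab (0.751), Hspa4 (1.08), Echs1 (0.995), Acot2 (1.12) and Cxcr4 (0.644).

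With the hybridization controls in the model the scores turned for monocytes (0.0968), T cells (-0.108), interferon (0.0781), inflammation (0.0532), NRF2 (0.274) and unfolded protein response (0.205). They also turned for glucocorticoid (-0.00745), cell cycle (0.0582), insulin (-0.0611) and ubiquitin (0.00076). The natural killer list turned in camera direction only, its score difference staying negative (-0.00184). The genes Xpo7 (0.0382), Tmcc2 (0.116), Kel (0.0087) and Gypc (0.0692) turned too, and the cause of these turns was not tested. With the polyA controls the erythroid (-0.166), glucocorticoid (0.0261), autophagy (-0.0838) and insulin (-0.00396) lists turned in score or in camera direction, and the cause was not tested. The cause was not tested either where the erythroid and glucocorticoid scores turned in the brighter probe sets (-0.00369 and -0.0098). Nor was it tested for the insulin list. That list turned in camera direction only with the erythroid covariate (score difference 0.0053), and in score without _s_at, _x_at and _a_at probe sets (-0.00307). The neutrophil minus T cell covariate turned NRF2 (0.00279) and insulin (-0.00226), and centring in SD units turned erythroid (-0.059), glucocorticoid (-0.0421) and insulin (-0.0668), the cause again not tested.

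Without 1 array, with fewer samples, these values turned, given as lowest to highest: Tmcc2 -0.891 to 0.672, Ctrb1 -0.475 to 0.877, glucocorticoid -0.223 to 0.215, insulin -0.0436 to 0.129, erythroid -0.173 to 0.17, neutrophil -0.119 to 0.325, NRF2 -0.287 to 0.15, cell cycle -0.13 to 0.0198, ubiquitin -0.362 to 0.153, monocyte -0.501 to 0.189, inflammation -0.237 to 0.116, glycolysis -0.243 to 0.0995 and unfolded protein response -0.257 to 0.234. The ribosomal score stayed between -1.35 and -1.12, and the ribosomal and MHC class II lists kept their camera calls without any 1 array. Signal over background was not used here, so what dim probe sets limit was tested only by keeping the brighter ones.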

Other observations

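The genes of the lists below were taken by smallest unadjusted p within their list, by the rule for naming genes. The lists, and the other values in this part, were picked after the results were seen, and no tests were added for them. None of the genes passed the limma threshold.

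Genes of autophagy with the smallest unadjusted p in their list had positive values: Wipi1, a phosphoinositide-binding protein of autophagosome formation (1.52 ± 0.42 SD units, SE), Map1lc3a, an LC3 gene (1.5 ± 0.433, 0 after quantile normalization), and Optn, a mitophagy receptor (1.44 ± 0.458). Among glucocorticoid-responsive genes, Pik3ip1, an inhibitor of PI3-kinase, differed by 1.56 ± 0.399 and the chemokine receptor gene Cxcr4 by -1.49 ± 0.439 (0 after quantile normalization and 0.644 after median centring). In fatty acid oxidation, the thioesterase gene Acot2 differed by -1.54 ± 0.582 (0.303 after quantile normalization and 1.12 after median centring) and the thiolase gene Acaa2 by -1.31 ± 0.512.

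Ldhb, the lactate dehydrogenase B gene, read 6.86 in mulberry replicates 2 to 4 and 6.95 to 6.98 on the other 5 arrays (difference -1.44 ± 0.457 SD units). Kel, a blood group gene of red cells, read 9.66 in high-fat replicate 1 and 9.63 to 9.64 elsewhere. The first principal component of the SD-scaled values held 25.5% of the variance (two-sided exact permutation p = 0.571 between diets) and the second 15.1% (exact permutation p = 0.0571). The ratio of 3' to 5' probe sets was compared between the diets too (exact permutation p = 0.771 for beta-actin and 0.371 for Gapdh).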
